A study of Mus musculus with 12 samples.

How the data were processed

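RNA was measured in 12 libraries of C57BL/6 mice, 3 each of WT HSC, Tg HSC, WT MPP and Tg MPP, where Tg mice carry an EPO transgene and WT mice are littermates. Per the labels, RNA was isolated with a micro column kit, cDNA was made with the SMARTer chemistry, with a pre-amplification for HSC and not for MPP, sheared by ultrasound and made into libraries with NEBNext reagents, so that cell type and preparation cannot be separated. The authors' processing notes name FastQC, BWA 0.7.8, featureCounts 1.4.4, DESeq2 1.4.0, DESeq and the mm10 genome, without the role or order of each; strandedness, annotation release and sort gates are not given there. The deposited tables, 1 for each cell type, hold for each gene a signal per library, which is the read count divided by 1 size factor per library by the authors, rounded to 1 decimal, and the means of these signals. They also hold the authors' log2 fold change and its standard error, Tg over WT in HSC (99.8% of genes with the sign of Tg minus WT) and WT over Tg in MPP (0.09%), and the authors' p-value and adjusted p-value from DESeq2, rounded to 3 decimals. In all, 24598 genes are listed for HSC and 23088 for MPP. Shorter sheets repeat the 6629 and 3801 genes with an adjusted p under 0.1, in MPP with the deposited ratio of the authors' Tg and WT means.

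Whole read counts were recovered by finding, for each library, the value of 1 read in normalised units; at least 99.97% of values in each library were whole within 0.051. On simulated data the same steps returned 100% of 147588 and 138528 values. The libraries held 17318644 to 30201268 reads in genes, and the limit of 3 reads lay at 0.0993 to 0.173 CPM (counts per 1e6 reads). Replicates differed by a chi-square per degree of freedom of 6.96 to 24.6, above counting error. Mitochondrial genes held 0.861 to 1.81% of reads. No library was left out.

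Tg was compared with WT within each cell type by limma 3.58.1 (trend) in R 4.3.3 on log2 of the normalised value plus 1, for genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference of the transgene effect between HSC and MPP, and WT MPP against WT HSC, were fitted with edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered reads of 22057 genes listed in both tables. The plan written before the data were examined had edgeR on counts, with limma for normalised values as the fallback, and no fit across tables normalised separately; since whole reads could be recovered, the edgeR fits across tables were made, a departure decided after the data were seen. The comparisons, 36 gene lists, rule for named genes and the first set of alternatives were chosen before the data were examined. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, leaving 35 lists; the sex-linked list was a check. The lists cover erythroid, megakaryocyte, stem cell, progenitor, lymphoid and myeloid genes, cell cycle, heme and iron, EPO receptor targets, stress, metabolism, ribosomes, mitochondria, signalling, inflammation and niche, and markers of other cell types. List tests of the difference and of WT MPP against WT HSC, on voom values, were added after the data were seen.

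Named genes were Epo and Epor, the 8 with the smallest p-values in each direction among those whose libraries did not overlap, leaving out unnamed gene models, the 2 members with the smallest p-values of each called list, and a fixed panel of 21 genes; for the difference the 5 with the smallest p-values in each direction and the panel, and for WT MPP against WT HSC the panel. Some results under these rules are not reported here. Further list members were named as examples after their values were seen. Alternatives were pseudocounts of 0.5 and 5, no filter, a filter of 5 CPM in 3 libraries, TMM and size factor scaling, edgeR, DESeq2 1.42.0 and voom with quality weights on recovered reads, 1 fit of all 12 libraries, thresholds of 0.1 and of 2-fold, a replicate block, and leaving out each library. Scaling to total reads, cyclic loess and a limma fit of the difference were added after seeing the data. With 3 libraries against 3 an exact permutation cannot give a p-value under 0.1, so models that share the spread across genes were used. On simulated data the fits called 4-fold changes in 93.9% in HSC, 92.4% in MPP, 77.3% for the difference between cell types and 90.9% for WT MPP against WT HSC, 2-fold changes in 61.2% in HSC, 64.2% in MPP, 49.3% for the difference between cell types and 71.6% for WT MPP against WT HSC, and 1.5-fold changes in 41.8% in HSC, 49.3% in MPP, 17.9% for the difference between cell types and 37.3% for WT MPP against WT HSC. False calls were 11 of 142 calls in HSC, 12 of 149 in MPP, 9 of 105 for the difference and 8 of 141 for WT MPP against WT HSC, somewhat above the nominal 0.05. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.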

Results

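RNA sequencing libraries were analysed from hematopoietic stem cells (HSC) and multipotent progenitors (MPP) of C57BL/6 mice. Some mice carried an erythropoietin (EPO) transgene (Tg), and the others were their wild-type (WT) littermates. EPO is the hormone that drives red blood cell production, and the mice model chronic erythroid stress. There were 4 groups, WT HSC, Tg HSC, WT MPP and Tg MPP, with 3 libraries each. The 6 HSC libraries held 20714105 to 30201268 reads in genes, and the 6 MPP libraries 17318644 to 25218436. A count of 0 allowed a level of up to 0.0993 to 0.173 CPM (counts per 1e6 reads), a limit that covers counting error only. The labels do not say whether the replicates are separate mice, or whether HSC and MPP libraries come from the same mice, and all libraries were treated as independent. The p-values thus measure the spread between these samples, which may be technical. The 10 most abundant genes took 5.06 to 5.61% of the normalised reads in WT libraries and 5.86 to 8.86% in Tg libraries. Values are the mean ± SD of 3 libraries in normalised reads. Effects, in brackets after gene names, are log2 fold changes of Tg over WT, with their standard error (SE) where given. They were computed on log2 of the normalised reads plus 1, which understates the fold of genes with few reads. Positions are mm10 coordinates.

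The first comparison asked what the transgene changed in HSC. The Tg HSC libraries held far more reads of red cell lineage genes than the WT HSC libraries. Alas2, which encodes the enzyme that starts erythroid heme synthesis, was at 104888 ± 12956 against 15338 ± 979.9 normalised reads (log2 fold change 2.77, SE 0.095, limma adjusted p = 2.80e-08). Hbb-b1, an adult beta globin gene, was at 500228 ± 57329.7 against 95283 ± 9649 normalised reads (log2 fold change 2.39, SE 0.11). Of stem cell identity genes 33 of 40 fell, among them Procr, a receptor gene used to define HSC (log2 fold change -1.4, SE 0.12). Genes of G2 and mitosis rose in 51 of 52 cases, with the proliferation marker Mki67 at 26919.8 ± 1446 against 10893 ± 766 normalised reads (log2 fold change 1.31, SE 0.075). Macrophage markers rose as well, 17 of 18. In Alas2, Hbb-b1, Procr and Mki67 all 3 Tg libraries lay on 1 side of all 3 WT libraries.

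Of the 25 measured terminal erythroid genes, 25 rose and 0 fell, 25 and 0 adjusted over the list alone, with a median of 2.09. Terminal erythroid genes had a camera adjusted p of 1.32e-28, and adjusted p = 0.138 with an estimated correlation. The smallest log2 fold change was 1.16, in Gypc. Among them were the membrane skeleton gene Epb4.2 (2.48), the anion exchanger gene Slc4a1 (2.29) and the alpha globin genes Hba-a1 (2.15) and Hba-a2 (2.23). The alpha globin genes are nearly identical, as are Hbb-b1 and Hbb-b2 (2.25), so reads may be exchanged between copies. Among 27 early erythroid regulators and receptors measured, 20 rose and 5 fell, 20 and 5 adjusted over the list alone, with a median of 1.23. Early erythroid regulators and receptors had a camera adjusted p of 5.60e-10, and adjusted p = 0.138 with an estimated correlation. The erythroid transcription factor genes Gata1 (1.73) and Klf1 (2.46) and the blood group antigen gene Rhag (2.15) rose. The EPO receptor gene Epor (1.0, limma adjusted p = 7.13e-05) rose as well, to 1519 ± 106 against 765 ± 112 normalised reads. Gata2 (-0.43), Lmo2 (-0.48), Ldb1 (-0.66), Cbfa2t3 (-0.27) and Trib2 (-0.98) fell, of which Gata2 and Lmo2 encode regulators of stem and progenitor cells. Epo itself was not listed in either table.

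Of the 14 measured heme synthesis genes, 14 rose and 0 fell, 14 and 0 adjusted over the list alone, with a median of 1.27. Heme synthesis genes had a camera adjusted p of 1.21e-13, and adjusted p = 0.138 with an estimated correlation. Among 25 iron handling genes measured, 16 rose and 1 fell, 16 and 1 adjusted over the list alone, with a median of 0.64. Iron handling genes had a camera adjusted p of 5.29e-07, and adjusted p = 0.138 with an estimated correlation. Iron enters cells through the transferrin receptor, and its gene Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794) was at 34517 ± 2658 against 6071 ± 342 normalised reads (log2 fold change 2.51, SE 0.077, limma adjusted p = 1.95e-08). The mitochondrial iron importer gene Slc25a37 (1.75) also rose. Of the 22 measured EPO receptor and STAT5 target genes, 7 rose and 4 fell, 8 and 4 adjusted over the list alone, with a median of 0.12 (-0.13 under scaling to total reads). EPO receptor and STAT5 target genes had a camera adjusted p of 0.15, and adjusted p = 0.335 with an estimated correlation, against 2.94e-04 with fry (from 2.94e-04 to 0.335 over its alternatives). Fam132b, the gene of the iron-regulating hormone erythroferrone (4.18), the survival gene Bcl2l1 (2.02) and the feedback inhibitor gene Cish (0.70, 1711 ± 109 against 1049 ± 24 normalised reads) rose. Pim1 (0.88) rose with Tg and WT libraries that overlapped, and Socs2 (-1.13), Pim3 (-0.90), Spred2 (-0.64) and Ccnd2 (-0.45) fell. Socs3 stood at 0.45 (limma adjusted p = 0.114) and passed under cyclic loess (0.0328; from 0.0328 to 0.467 over its alternatives).

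Among the 8 genes that rose with the smallest p-values was Fam46c (ENSMUSG00000044468, chromosome 3, 100451628 to 100489324) at 39426 ± 3444 against 5087 ± 181 normalised reads (log2 fold change 2.95, SE 0.077). The pleckstrin family gene Plek2 (ENSMUSG00000021118, chromosome 12, 78888691 to 78906964) was at 1568 ± 32.2 against 139.5 ± 17.1 normalised reads (log2 fold change 3.49, SE 0.12). The cell cycle transcription factor gene E2f2 (ENSMUSG00000018983, chromosome 4, 136172394 to 136196057) had a log2 fold change of 1.95 (SE 0.071). The others were Tfrc (2.51), Alas2 (2.77), Epb4.2 (2.48), Apol11b (3.25) and Tmcc2 (2.44). The 8 genes that fell with the smallest p-values were Sult1a1 (-2.03), Pygm (-2.36), Runx1t1 (-2.55), Plk2 (-1.99), Adck3 (-1.18), Lpar6 (-1.23), Clec1a (-1.37) and Efna1 (-2.20). Sult1a1 (ENSMUSG00000030711, chromosome 7, 126672865 to 126676432), a sulfotransferase gene on the stem cell list, was at 717 ± 41.1 against 2936 ± 145 normalised reads (SE 0.084).

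Among 45 S phase genes measured, 44 rose and 0 fell, 44 and 0 adjusted over the list alone, with a median of 0.83. Examples were Rrm2 (1.25) and E2f8 (1.37). S phase genes had a camera adjusted p of 3.11e-23, and adjusted p = 0.169 with an estimated correlation. Of the 52 measured genes of G2 and mitosis, 51 rose and 0 fell, 52 and 0 adjusted over the list alone, with a median of 1.02. Examples were Ube2c (1.46), Ccnb1 (1.32), Bub1 (1.32) and Mki67 (1.31). Genes of G2 and mitosis had a camera adjusted p of 6.71e-30, and adjusted p = 0.169 with an estimated correlation. Among 40 stem cell identity genes measured, 0 rose and 33 fell, 0 and 34 adjusted over the list alone, with a median of -0.80. Stem cell identity genes had a camera adjusted p of 1.52e-17, and adjusted p = 0.138 with an estimated correlation. Those that fell included the transcription factor genes Hlf (-0.94), Mecom (-0.89), Prdm16 (-0.95) and Hoxb5 (-1.33) and the surface receptor genes Procr (-1.4) and Slamf1 (-0.50). The gene of von Willebrand factor, Vwf (-0.83), and the cell cycle inhibitor gene Cdkn1c (-1.50) fell too. The stem cell genes Ly6a (-0.013), Tek (-0.0078) and Pdzk1ip1 (-0.046) did not pass. Of the 12 measured multipotent progenitor markers, 5 rose and 1 fell, 6 and 1 adjusted over the list alone, with a median of 0.23 (-0.019 under scaling to total reads). Multipotent progenitor markers had a camera adjusted p of 0.0329, and adjusted p = 0.4 with an estimated correlation, against 0.0779 under a filter of 5 CPM, 0.127 under scaling to total reads and 0.247 under cyclic loess (median 0.11). For progenitor markers camera gave adjusted p of 0.0643 without WT_HSC replicate 2 (from 0.011 to 0.4 over its alternatives). The cell cycle kinase gene Cdk6 (1.02) and Plac8 (0.53) rose. Cd34 was at 0.20 (limma adjusted p = 0.0331). Of the fits without 1 library, those without WT_HSC replicate 2 or Tg_HSC replicate 2 kept this call. It stood at -0.047 under scaling to total reads and -0.029 under cyclic loess (limma adjusted p from 0.0201 to 0.77 over its alternatives). Flt3 (0.26, limma adjusted p = 0.161) did not pass, with 0.0393 without WT_HSC replicate 3 (from 0.0393 to 0.96 over its alternatives).

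Among 30 genes of the unfolded protein and integrated stress responses measured, 23 rose and 2 fell, 23 and 2 adjusted over the list alone, with a median of 0.50. Genes of the unfolded protein and integrated stress responses had a camera adjusted p of 4.40e-09, and adjusted p = 0.138 with an estimated correlation. The folate pathway gene Mthfd2 (2.47), the asparagine synthetase gene Asns (2.0) and the glutathione-degrading enzyme gene Chac1 (2.69) led this list, and the stress sensor gene Ern1 (-0.81) fell. Of the 29 measured oxidative stress genes, 16 rose and 4 fell, 18 and 5 adjusted over the list alone, with a median of 0.30. Oxidative stress genes had a camera adjusted p of 8.04e-04, and adjusted p = 0.433 with an estimated correlation, against 0.0684 under cyclic loess (median 0.083) (from 2.37e-04 to 0.433 over its alternatives). Scaling to total reads gave a median of 0.049 for these genes and 0.025 for ribosome biogenesis genes. The oxidative stress list was led by the heme oxygenase gene Hmox1 (1.97), the catalase gene Cat (1.33) and Gpx1 (1.35). Among 37 ribosome biogenesis genes measured, 23 rose and 0 fell, 25 and 0 adjusted over the list alone, with a median of 0.28. Examples were Rrp12 (0.57) and Nolc1 (0.55). Ribosome biogenesis genes had a camera adjusted p of 1.46e-06, and adjusted p = 0.169 with an estimated correlation. Of the 80 measured cytosolic ribosomal protein genes, 0 rose and 27 fell, 0 and 22 adjusted over the list alone, with a median of -0.25. Examples were Rpl32 (-0.42) and Rpl22 (-0.40). Cytosolic ribosomal protein genes had a camera adjusted p of 3.81e-06, and adjusted p = 0.433 with an estimated correlation. Among 66 nuclear genes of the respiratory chain measured, 18 rose and 0 fell, 17 and 0 adjusted over the list alone, with a median of 0.17 (-0.081 under scaling to total reads). Nuclear genes of the respiratory chain had a camera adjusted p of 1.43e-04, and adjusted p = 0.57 with an estimated correlation, against 0.107 under scaling to total reads, 0.176 under cyclic loess (median 0.044) and 0.153 with fry (from 1.21e-08 to 0.57 over its alternatives). Of the 23 measured hypoxia-inducible genes, 0 rose and 7 fell, 0 and 6 adjusted over the list alone, with a median of -0.28. Examples were Rora (-1.14) and Slc2a1 (-0.43). Hypoxia-inducible genes had a camera adjusted p of 0.0167, and adjusted p = 0.151 with an estimated correlation. Among 28 lymphoid priming genes measured, 2 rose and 13 fell, 2 and 14 adjusted over the list alone, with a median of -0.40. Of the 28, 10 are on other lists, so this is not a separate result: Cd79a (-1.70) is also a B cell marker. Mn1 (-1.09) fell too. Lymphoid priming genes had a camera adjusted p of 6.69e-04, and adjusted p = 0.143 with an estimated correlation. Dntt was at -0.69 (limma adjusted p = 0.0395). Of the fits without 1 library, those without WT_HSC replicate 2 or Tg_HSC replicate 3 kept this call (limma adjusted p from 0.00787 to 0.146 over its alternatives).

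Markers of other cell types also moved with the genotype. Of the 18 measured macrophage markers, 17 rose and 0 fell, 17 and 1 adjusted over the list alone, with a median of 1.70. Macrophage markers had a camera adjusted p of 5.05e-11, and adjusted p = 0.138 with an estimated correlation. The complement genes C1qa (2.59) and C1qb (2.62), the scavenger receptor gene Marco (3.63) and the adhesion gene Vcam1 (2.24, 4102 ± 454 against 870 ± 129 normalised reads) rose. Mpeg1 (-0.37) did not pass over all genes. Among 14 B cell markers measured, 0 rose and 11 fell, 0 and 12 adjusted over the list alone, with a median of -1.52. B cell markers had a camera adjusted p of 5.29e-07, and adjusted p = 0.138 with an estimated correlation. Vpreb3, a gene of precursor B cells, was at 99.1 ± 17.3 against 399.7 ± 39 normalised reads (log2 fold change -2.01). Of the 19 measured markers of mature neutrophils and monocytes, 9 rose and 0 fell, 9 and 0 adjusted over the list alone, with a median of 0.23 (-0.025 under scaling to total reads). Examples were Itgam (0.59) and Ccr2 (0.56). Markers of mature neutrophils and monocytes had a camera adjusted p of 5.11e-04, and adjusted p = 0.456 with an estimated correlation, against 0.23 under cyclic loess (median 0.088) and 0.0545 with fry (from 6.58e-06 to 0.456 over its alternatives). The abundant neutrophil genes S100a8 (0.042) and S100a9 (0.087) did not pass.

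Other lists did not pass camera in HSC. Among 29 megakaryocyte and platelet genes measured, 10 rose and 8 fell, 11 and 8 adjusted over the list alone, with a median of 0.17 (-0.077 under scaling to total reads). Megakaryocyte and platelet genes had a camera adjusted p of 0.326, and adjusted p = 0.519 with an estimated correlation, against 0.00375 with fry (from 0.00375 to 0.786 over its alternatives). The platelet integrin gene Itga2b (1.4) and Pf4 (1.57) rose. Of the 44 measured interferon-stimulated genes, 8 rose and 15 fell, 9 and 16 adjusted over the list alone, with a median of -0.10. Interferon-stimulated genes had a camera adjusted p of 0.284, and adjusted p = 0.456 with an estimated correlation, against 0.0216 under cyclic loess (median -0.20) (from 0.0216 to 0.456 over its alternatives). Isg15 (2.17) and Rsad2 (2.04) rose and Mx2 (-1.54) and Ifi44 (-1.08) fell. Among 23 niche adhesion and homing genes measured, 6 rose and 10 fell, 6 and 10 adjusted over the list alone, with a median of -0.18. Examples were Jam3 (-1.68) and Emcn (-1.66). Niche adhesion and homing genes had a camera adjusted p of 0.12, and adjusted p = 0.29 with an estimated correlation, against 0.0277 under cyclic loess (median -0.31) and 9.26e-04 with fry (from 9.26e-04 to 0.29 over its alternatives). Of the 27 measured quiescence regulators, 5 rose and 11 fell, 5 and 12 adjusted over the list alone, with a median of -0.42. Quiescence regulators had a camera adjusted p of 0.069, and adjusted p = 0.558 with an estimated correlation, against 0.0328 under cyclic loess (median -0.45). For quiescence regulators camera gave adjusted p of 0.0189 without WT_HSC replicate 1 (from 0.0189 to 0.558 over its alternatives). Among 30 NF-kB and inflammatory genes measured, 3 rose and 8 fell, 3 and 8 adjusted over the list alone, with a median of -0.13. NF-kB and inflammatory genes had a camera adjusted p of 0.138, and adjusted p = 0.436 with an estimated correlation. Of the 29 measured granulocyte-monocyte progenitor genes, 7 rose and 2 fell, 7 and 2 adjusted over the list alone, with a median of 0.17 (-0.085 under scaling to total reads). Granulocyte-monocyte progenitor genes had a camera adjusted p of 0.112, and adjusted p = 0.634 with an estimated correlation. For these progenitor genes camera gave adjusted p of 0.0147 without WT_HSC replicate 3 and 0.0216 without Tg_HSC replicate 1 (from 0.0147 to 0.763 over its alternatives). Mpo, the myeloperoxidase gene, was at 0.055 (limma adjusted p = 0.558). It stood at -0.20 under scaling to total reads and at -0.26 under cyclic loess (limma adjusted p from 0.00438 to 0.878 over its alternatives).

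Among 22 glycolysis genes measured, 3 rose and 4 fell, 3 and 4 adjusted over the list alone, with a median of -0.013. Glycolysis genes had a camera adjusted p of 0.55, and adjusted p = 0.747 with an estimated correlation, against 0.0137 under cyclic loess (median -0.18) (from 0.0137 to 0.747 over its alternatives). Of the 28 measured immediate early and heat shock genes, 5 rose and 8 fell, 6 and 9 adjusted over the list alone, with a median of -0.21. Immediate early and heat shock genes had a camera adjusted p of 0.326, and adjusted p = 0.634 with an estimated correlation. Among 30 cytokine and growth factor receptor genes measured, 3 rose and 8 fell, 3 and 8 adjusted over the list alone, with a median of -0.057. Cytokine and growth factor receptor genes had a camera adjusted p of 0.288, and adjusted p = 0.436 with an estimated correlation, against 0.0161 with fry (from 0.0161 to 0.442 over its alternatives). Of the 7 measured mitochondrially encoded genes, 0 rose and 4 fell, 1 and 4 adjusted over the list alone, with a median of -0.44. Mitochondrially encoded genes had a camera adjusted p of 0.0968, and adjusted p = 0.558 with an estimated correlation, against 0.0373 under a replicate block and 0.00984 under cyclic loess (median -0.68). For mitochondrially encoded genes camera gave adjusted p of 0.0142 without WT_HSC replicate 3 and 0.0329 without Tg_HSC replicate 1 (from 0.00984 to 0.558 over its alternatives). Among 27 TGF-beta and BMP pathway genes measured, 3 rose and 10 fell, 3 and 10 adjusted over the list alone, with a median of -0.39. TGF-beta and BMP pathway genes had a camera adjusted p of 0.0511, and adjusted p = 0.228 with an estimated correlation, against 0.0349 under a replicate block and 0.015 with fry. For TGF-beta and BMP genes camera gave adjusted p of 0.025 without WT_HSC replicate 1 and 0.0323 without Tg_HSC replicate 1 (from 0.015 to 0.228 over its alternatives). Of the 23 measured p53 target genes, 6 rose and 4 fell, 8 and 4 adjusted over the list alone, with a median of -0.15, a mean of 0.04 and a test direction of higher. Examples were Pmaip1 (1.84) and Plk2 (-1.99). The p53 target genes had a camera adjusted p of 0.664, and adjusted p = 0.709 with an estimated correlation.

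Among 18 T and NK cell markers measured, 1 rose and 3 fell, 1 and 2 adjusted over the list alone, with a median of -0.24. T and NK cell markers had a camera adjusted p of 0.215, and adjusted p = 0.682 with an estimated correlation. Of the 12 measured endothelial and stromal markers, 1 rose and 4 fell, 3 and 4 adjusted over the list alone, with a median of -0.24. Endothelial and stromal markers had a camera adjusted p of 0.296, and adjusted p = 0.456 with an estimated correlation, against 0.00429 with fry (from 0.00429 to 0.914 over its alternatives). Among 15 markers of mast cells, basophils and eosinophils measured, 5 rose and 0 fell, 3 and 0 adjusted over the list alone, with a median of 0.14 (-0.19 under scaling to total reads). Markers of mast cells, basophils and eosinophils had a camera adjusted p of 0.15, and adjusted p = 0.618 with an estimated correlation. For mast cell markers camera gave adjusted p of 0.0228 without WT_HSC replicate 3 (from 0.0228 to 0.618 over its alternatives). Of the 15 measured markers of dendritic cells and MHC class II, 4 rose and 7 fell, 4 and 7 adjusted over the list alone, with a median of -0.33. Markers of dendritic cells and MHC class II had a camera adjusted p of 0.296, and adjusted p = 0.618 with an estimated correlation.

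Of 14922 genes tested in HSC, 5452 changed (limma, adjusted p under 0.05), 2929 upward and 2523 downward, and 695 and 703 of them by at least 2-fold. In 49.6% of the tested genes the Tg and WT libraries did not overlap, where chance gives 10%. The authors' deposited table holds 5609 genes with an adjusted p-value under 0.05, and 5330 of the genes called here were among them in the same direction. Camera called 18 of 35 lists, 13 higher and 5 lower. With an estimated correlation camera called 0, with 10 at an unadjusted p under 0.05, and fry called 22. Directions are relative to the authors' scaling: scaling to total reads, chosen after seeing the data, moved the median of all genes by -0.25, and the list medians by about as much, and gave 1509 genes upward and 5581 downward. Log2 fold changes also grew with expression level, from a median of -0.23 in the lowest 10% of genes to 0.19 in the highest 10%.

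**Figure D1:**
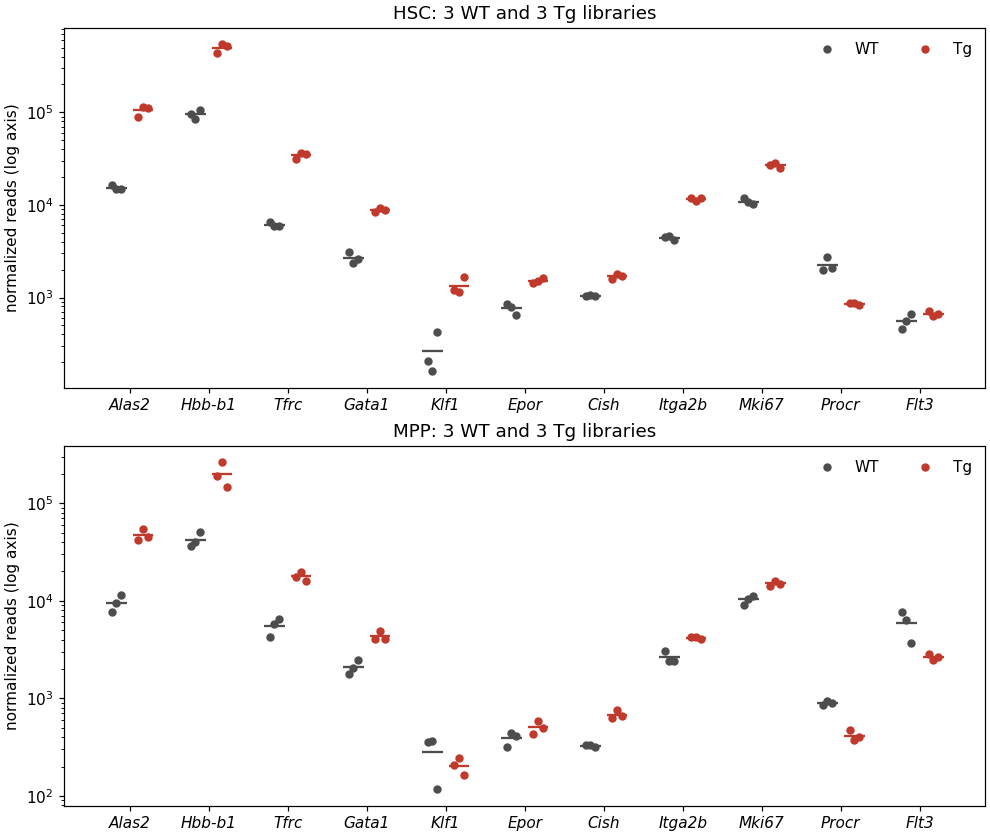
Normalised reads of 11 named genes in each of the 12 libraries on a log axis, with 1 point per library and the mean of each group of 3. Alas2, Hbb-b1 and Tfrc lie higher in every Tg library than in every WT library of the same cell type, and Procr lies lower.

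**Figure D2:**
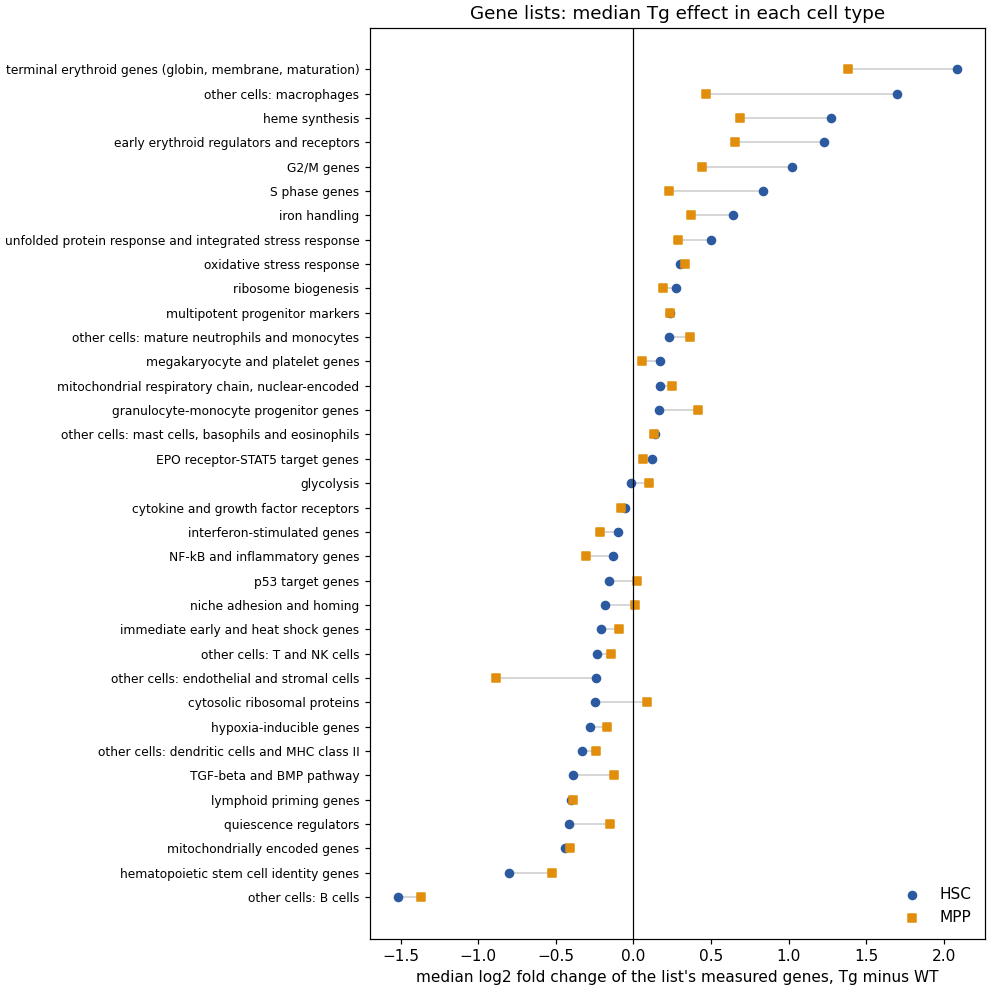
Median log2 fold change (Tg over WT) of each of the 35 gene lists in HSC and in MPP under the authors' scaling; small medians, such as those of the EPO receptor and STAT5 targets, change sign under scaling to total reads. Terminal erythroid genes stand at 2.09 in HSC and 1.39 in MPP, and stem cell identity genes at -0.80 and -0.52.

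The same question was asked of MPP. The Tg MPP libraries also held more reads of erythroid genes than the WT MPP libraries, with Alas2 at 46913 ± 6697 against 9524 ± 1832 normalised reads (log2 fold change 2.31, SE 0.14, limma adjusted p = 3.40e-05). Hbb-b1 was at 200203 ± 59417 against 42129 ± 7264 normalised reads (log2 fold change 2.22, SE 0.2). Of stem cell identity genes 26 of 40 fell, among them the transcription factor gene Hlf at 2967 ± 329.6 against 6718 ± 131 normalised reads (log2 fold change -1.18, SE 0.085). Of granulocyte-monocyte progenitor genes 16 of 29 rose, with the neutrophil protease gene Ctsg at 4079.7 ± 256 against 2195 ± 198 normalised reads (log2 fold change 0.90, SE 0.086). Of B cell markers 13 of 14 fell. Macrophage markers rose in 9 of 17 cases. In Alas2, Hbb-b1, Hlf and Ctsg all 3 Tg libraries lay on 1 side of all 3 WT libraries.

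Among 25 terminal erythroid genes measured, 25 rose and 0 fell, 25 and 0 adjusted over the list alone, with a median of 1.39. Terminal erythroid genes had a camera adjusted p of 1.01e-24, and adjusted p = 0.192 with an estimated correlation. The smallest log2 fold change was 0.55, again in Gypc. Of the 27 measured early erythroid regulators and receptors, 15 rose and 2 fell, 19 and 4 adjusted over the list alone, with a median of 0.65. Early erythroid regulators and receptors had a camera adjusted p of 8.26e-06, and adjusted p = 0.28 with an estimated correlation. Tfrc was at 17767 ± 2021 against 5479.8 ± 1149 normalised reads (log2 fold change 1.71, SE 0.15), and Gata1 (1.05), Gfi1b (0.57) and Tal1 (0.72) rose. Epor stood at 0.38 (limma adjusted p = 0.115). Klf1 was at 204 ± 39.5 against 280.2 ± 142 normalised reads, a log2 fold change of -0.30 (limma adjusted p = 0.628). Without WT_MPP replicate 3 Klf1 was at -0.84 and passed (limma adjusted p from 0.0118 to 0.986 over its alternatives). Among 14 heme synthesis genes measured, 14 rose and 0 fell, 14 and 0 adjusted over the list alone, with a median of 0.69. Heme synthesis genes had a camera adjusted p of 3.14e-11, and adjusted p = 0.203 with an estimated correlation. Of the 25 measured iron handling genes, 11 rose and 0 fell, 11 and 0 adjusted over the list alone, with a median of 0.37. Examples were Slc25a37 (1.35) and Slc11a2 (0.60). Iron handling genes had a camera adjusted p of 9.32e-05, and adjusted p = 0.338 with an estimated correlation.

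Among 22 EPO receptor and STAT5 target genes measured, 5 rose and 2 fell, 5 and 3 adjusted over the list alone, with a median of 0.063 (-0.065 under scaling to total reads). EPO receptor and STAT5 target genes had a camera adjusted p of 0.217, and adjusted p = 0.338 with an estimated correlation, against 0.00198 with fry (from 0.00198 to 0.434 over its alternatives). Fam132b (3.22), Podxl (2.83) and Bcl2l1 (1.53) rose, as did Cish (1.05, 683 ± 68.1 against 327 ± 10.2 normalised reads). The stem cell factor receptor gene Kit (-0.31) and Dok2 (-0.50) fell, and Pim1 (0.21) and Socs3 (0.33) did not pass. Among the genes that rose with the smallest p-values were Cd300e (3.80), Fcgr4 (2.92), Mthfd2 (1.43), Fam46c (2.66), Apol11b (2.83), Epb4.1 (1.69) and Bpgm (2.11). The myeloid receptor gene Cd300e (ENSMUSG00000048498, chromosome 11, 115051917 to 115062177) was at 580.2 ± 19.1 against 40.7 ± 2.82 normalised reads (SE 0.14). The antibody receptor gene Fcgr4 (ENSMUSG00000059089, chromosome 1, 171018920 to 171029761) was at 938 ± 102 against 123 ± 5.29 normalised reads (SE 0.12). Among those that fell were Paqr5 (-1.43), Hlf (-1.18), Adam22 (-1.39), Emcn (-2.01), Ifi44 (-1.37), Slc16a12 (-1.90) and Fcrla (-1.78). Hlf (ENSMUSG00000003949, chromosome 11, 90336536 to 90390895) is also on the stem cell list.

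Of the 40 measured stem cell identity genes, 1 rose and 26 fell, 2 and 29 adjusted over the list alone, with a median of -0.52. Examples were Procr (-1.12), Mecom (-0.98), Fgd5 (-1.47) and Trpc6 (-1.65). Stem cell identity genes had a camera adjusted p of 1.35e-14, and adjusted p = 0.158 with an estimated correlation. The stress response gene Nupr1 (1.0) rose against the list, and Slamf1 (0.17), Gata2 (-0.11), Vwf (-0.30) and Cdkn1c (-0.92) did not pass. Vwf passed under scaling to total reads (limma adjusted p = 0.0283; from 0.0283 to 0.291 over its alternatives). Without Tg_MPP replicate 3 Cdkn1c passed (limma adjusted p = 0.0489). With all libraries it passed in edgeR on all 12 (0.0132), in voom with quality weights (0.0268) and under scaling to total reads (0.034; adjusted p from 0.0132 to 0.174 over its alternatives). Among 52 genes of G2 and mitosis measured, 42 rose and 0 fell, 48 and 0 adjusted over the list alone, with a median of 0.44. Examples were Ube2c (0.92), Aurka (0.79) and Mki67 (0.55). Genes of G2 and mitosis had a camera adjusted p of 3.93e-22, and adjusted p = 0.192 with an estimated correlation. Of the 45 measured S phase genes, 19 rose and 0 fell, 27 and 1 adjusted over the list alone, with a median of 0.23. Examples were E2f8 (0.66), Nasp (0.47) and Rrm2 (0.52). S phase genes had a camera adjusted p of 1.53e-08, and adjusted p = 0.192 with an estimated correlation. Among 12 multipotent progenitor markers measured, 5 rose and 2 fell, 7 and 3 adjusted over the list alone, with a median of 0.23. Multipotent progenitor markers had a camera adjusted p of 0.15, and adjusted p = 0.434 with an estimated correlation, against 0.0242 with fry (from 0.0242 to 0.743 over its alternatives). Cd48 (0.58) rose, a call not made by edgeR on all 12 libraries (adjusted p = 0.0528; from 1.76e-10 to 0.0528 over its alternatives). Cd34 (-0.36, limma adjusted p = 0.0122) fell. For Cd34 limma gave adjusted p of 0.0658 without WT_MPP replicate 2 and 0.0538 without Tg_MPP replicate 2 (from 3.36e-04 to 0.0658 over its alternatives).

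Of the 29 measured granulocyte-monocyte progenitor genes, 16 rose and 0 fell, 18 and 0 adjusted over the list alone, with a median of 0.42. Granulocyte-monocyte progenitor genes had a camera adjusted p of 2.01e-08, and adjusted p = 0.192 with an estimated correlation. Ly6c2 (0.97), the transcription factor gene Cebpb (1.27) and the macrophage growth factor receptor gene Csf1r (1.03) rose. Mpo also rose, to 106870 ± 5737 against 76249 ± 6127 normalised reads (log2 fold change 0.49, limma adjusted p = 0.00537). Its call was absent under cyclic loess (0.26, limma adjusted p = 0.074; from 6.48e-07 to 0.074 over its alternatives). Among 28 lymphoid priming genes measured, 1 rose and 13 fell, 2 and 14 adjusted over the list alone, with a median of -0.39. Again 10 of the 28 are on other lists, as are Cd79a (-1.53, B cells) and Ccr9 (-1.06, dendritic cells). Lymphoid priming genes had a camera adjusted p of 1.50e-05, and adjusted p = 0.158 with an estimated correlation. Flt3 was at 2678 ± 192 against 5952 ± 2056 normalised reads (log2 fold change -1.09, limma adjusted p = 0.00966). It was not called by edgeR (adjusted p = 0.0557; from 7.91e-05 to 0.11 over its alternatives), and Dntt (0.19) did not pass.

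Of the 30 measured genes of the unfolded protein and integrated stress responses, 16 rose and 1 fell, 19 and 1 adjusted over the list alone, with a median of 0.29. Examples were Chac1 (1.49), Trib3 (1.48) and Mthfd2 (1.43). Genes of the unfolded protein and integrated stress responses had a camera adjusted p of 7.43e-08, and adjusted p = 0.158 with an estimated correlation. Among 28 oxidative stress genes measured, 13 rose and 1 fell, 17 and 1 adjusted over the list alone, with a median of 0.33. Examples were Cat (0.77) and Gclm (0.58). Oxidative stress genes had a camera adjusted p of 8.85e-07, and adjusted p = 0.338 with an estimated correlation. Of the 37 measured ribosome biogenesis genes, 9 rose and 0 fell, 13 and 0 adjusted over the list alone, with a median of 0.19. Examples were Nolc1 (0.42) and Rrp12 (0.33). Ribosome biogenesis genes had a camera adjusted p of 1.07e-06, and adjusted p = 0.192 with an estimated correlation. Among 66 nuclear genes of the respiratory chain measured, 9 rose and 0 fell, 8 and 0 adjusted over the list alone, with a median of 0.25. Nuclear genes of the respiratory chain had a camera adjusted p of 4.92e-07, and adjusted p = 0.447 with an estimated correlation, against 0.141 with fry (from 1.47e-15 to 0.447 over its alternatives). Of the 7 measured mitochondrially encoded genes, 0 rose and 4 fell, 0 and 6 adjusted over the list alone, with a median of -0.41. Examples were mt-Nd4 (-0.50) and mt-Nd5 (-0.48). Mitochondrially encoded genes had a camera adjusted p of 0.00203, and adjusted p = 0.338 with an estimated correlation, against 0.0633 with fry (from 5.34e-05 to 0.338 over its alternatives). For mt-Nd4 edgeR on all 12 libraries gave an adjusted p of 0.0849 (from 4.92e-05 to 0.0849 over its alternatives). Among 80 cytosolic ribosomal protein genes measured, 2 rose and 0 fell, 0 and 0 adjusted over the list alone, with a median of 0.088 (-0.04 under scaling to total reads). Cytosolic ribosomal protein genes had a camera adjusted p of 0.047, and adjusted p = 0.674 with an estimated correlation, against 0.0582 under TMM, 0.185 under a filter of 5 CPM, 0.0538 under a replicate block, 0.15 under scaling to total reads, 0.809 under cyclic loess (median 0.032) and 0.386 with fry. For ribosomal protein genes camera gave adjusted p of 0.136 without WT_MPP replicate 2, 0.08 without WT_MPP replicate 3, 0.31 without Tg_MPP replicate 1 and 0.286 without Tg_MPP replicate 2 (from 1.19e-06 to 0.809 over its alternatives). Of the 23 measured hypoxia-inducible genes, 1 rose and 3 fell, 1 and 4 adjusted over the list alone, with a median of -0.17. Hypoxia-inducible genes had a camera adjusted p of 0.0408, and adjusted p = 0.228 with an estimated correlation, against 0.0522 under a filter of 5 CPM and 0.0918 under cyclic loess (median -0.16). For hypoxia-inducible genes camera gave adjusted p of 0.0698 without WT_MPP replicate 2, 0.106 without WT_MPP replicate 3, 0.0505 without Tg_MPP replicate 1 and 0.0635 without Tg_MPP replicate 3 (from 0.0197 to 0.228 over its alternatives).

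Among 44 interferon-stimulated genes measured, 6 rose and 19 fell, 7 and 21 adjusted over the list alone, with a median of -0.21. Interferon-stimulated genes had a camera adjusted p of 8.26e-06, and adjusted p = 0.192 with an estimated correlation. Ifi44 (-1.37), Oas2 (-1.30) and Irf7 (-0.88) fell and Rsad2 (1.80) and Isg15 (1.66) rose. Of the 30 measured NF-kB and inflammatory genes, 2 rose and 5 fell, 3 and 7 adjusted over the list alone, with a median of -0.30. Examples were Ccl4 (-0.68) and Ccl3 (-0.56), both chemokine genes. NF-kB and inflammatory genes had a camera adjusted p of 0.0375, and adjusted p = 0.28 with an estimated correlation. For NF-kB genes camera gave adjusted p of 0.08 without WT_MPP replicate 3 and 0.0886 without Tg_MPP replicate 1 (from 0.0141 to 0.28 over its alternatives). Among 17 macrophage markers measured, 9 rose and 0 fell, 9 and 0 adjusted over the list alone, with a median of 0.47. Examples were C1qb (1.51) and Cd68 (0.74). Macrophage markers had a camera adjusted p of 2.42e-04, and adjusted p = 0.338 with an estimated correlation. Vcam1 (-0.026), Fcna (0.057) and Mrc1 (0.011) did not pass. Of the 14 measured B cell markers, 0 rose and 13 fell, 0 and 14 adjusted over the list alone, with a median of -1.37. Pax5 was at -2.17. B cell markers had a camera adjusted p of 2.18e-11, and adjusted p = 0.192 with an estimated correlation. Among 19 markers of mature neutrophils and monocytes measured, 8 rose and 0 fell, 9 and 0 adjusted over the list alone, with a median of 0.36. Examples were Fn1 (1.31) and Ccr2 (1.03). Markers of mature neutrophils and monocytes had a camera adjusted p of 3.01e-05, and adjusted p = 0.4 with an estimated correlation, against 0.0833 with fry (from 7.85e-08 to 0.4 over its alternatives). S100a8 (-0.033) and S100a9 (-0.033) did not pass.

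Of the 11 measured endothelial and stromal markers, 0 rose and 3 fell, 1 and 3 adjusted over the list alone, with a median of -0.88. Examples were Cxcl12 (-2.66) and Emcn (-2.01). Endothelial and stromal markers had a camera adjusted p of 0.00642, and adjusted p = 0.192 with an estimated correlation. Among 16 markers of mast cells, basophils and eosinophils measured, 5 rose and 0 fell, 5 and 1 adjusted over the list alone, with a median of 0.13. Examples were Cma1 (3.43) and Gzmb (1.87). Markers of mast cells, basophils and eosinophils had a camera adjusted p of 0.0426, and adjusted p = 0.465 with an estimated correlation, against 0.0616 under voom, 0.0644 under voom with size factors and 0.0585 with fry. For mast cell markers camera gave adjusted p of 0.273 without WT_MPP replicate 1, 0.0725 without Tg_MPP replicate 2 and 0.0635 without Tg_MPP replicate 3 (from 0.00366 to 0.465 over its alternatives). Their median was -0.02 without WT_MPP replicate 1 and 0.036 without Tg_MPP replicate 2. Of the 16 measured markers of dendritic cells and MHC class II, 1 rose and 6 fell, 1 and 6 adjusted over the list alone, with a median of -0.24. Examples were Ccr9 (-1.06) and Siglech (-0.73). Markers of dendritic cells and MHC class II had a camera adjusted p of 0.0375, and adjusted p = 0.28 with an estimated correlation, against 0.12 under a filter of 5 CPM. For dendritic cell markers camera gave adjusted p of 0.106 without WT_MPP replicate 3 and 0.122 without Tg_MPP replicate 3 (from 0.0141 to 0.28 over its alternatives). Among 18 T and NK cell markers measured, 3 rose and 2 fell, 3 and 2 adjusted over the list alone, with a median of -0.15. T and NK cell markers had a camera adjusted p of 0.334, and adjusted p = 0.781 with an estimated correlation. For T and NK markers camera gave adjusted p of 0.0186 without Tg_MPP replicate 2 (from 0.0186 to 0.838 over its alternatives).

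Other lists did not pass camera in MPP. Of the 28 measured megakaryocyte and platelet genes, 2 rose and 3 fell, 2 and 3 adjusted over the list alone, with a median of 0.053 (-0.073 under scaling to total reads), a mean of -0.038 and a test direction of lower. Megakaryocyte and platelet genes had a camera adjusted p of 0.745, and adjusted p = 0.781 with an estimated correlation. Itga2b (0.67) rose, and Pf4 (0.34, limma adjusted p = 0.188) did not pass. Pf4 passed without Tg_MPP replicate 3 (limma adjusted p = 0.0217) and in voom with quality weights (0.0324; from 0.0217 to 0.474 over its alternatives). Among 23 niche adhesion and homing genes measured, 4 rose and 7 fell, 5 and 8 adjusted over the list alone, with a median of 0.0076 (-0.12 under scaling to total reads, -0.0076 under TMM, -0.085 under cyclic loess), a mean of -0.26 and a test direction of lower. Niche adhesion and homing genes had a camera adjusted p of 0.183, and adjusted p = 0.4 with an estimated correlation, against 0.0428 under cyclic loess and 0.00479 with fry (from 0.00479 to 0.4 over its alternatives). Of the 26 measured quiescence regulators, 4 rose and 5 fell, 5 and 7 adjusted over the list alone, with a median of -0.15. Quiescence regulators had a camera adjusted p of 0.334, and adjusted p = 0.431 with an estimated correlation, against 0.00997 with fry (from 0.00997 to 0.476 over its alternatives). Among 28 immediate early and heat shock genes measured, 3 rose and 5 fell, 6 and 7 adjusted over the list alone, with a median of -0.10. Immediate early and heat shock genes had a camera adjusted p of 0.442, and adjusted p = 0.467 with an estimated correlation. Of the 27 measured TGF-beta and BMP pathway genes, 1 rose and 3 fell, 1 and 3 adjusted over the list alone, with a median of -0.13. TGF-beta and BMP pathway genes had a camera adjusted p of 0.0979, and adjusted p = 0.28 with an estimated correlation, against 0.0218 with fry (from 0.0218 to 0.28 over its alternatives). Among 22 glycolysis genes measured, 6 rose and 5 fell, 6 and 5 adjusted over the list alone, with a median of 0.10 (-0.025 under scaling to total reads), a mean of -0.056 and a test direction of higher. Glycolysis genes had a camera adjusted p of 0.504, and adjusted p = 0.766 with an estimated correlation. Of the 24 measured p53 target genes, 4 rose and 3 fell, 5 and 4 adjusted over the list alone, with a median of 0.023 (-0.10 under scaling to total reads). The p53 target genes had a camera adjusted p of 0.791, and adjusted p = 0.783 with an estimated correlation. Among 30 cytokine and growth factor receptor genes measured, 3 rose and 6 fell, 3 and 6 adjusted over the list alone, with a median of -0.077. Cytokine and growth factor receptor genes had a camera adjusted p of 0.224, and adjusted p = 0.438 with an estimated correlation.

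Of 14417 genes tested in MPP, 2557 changed (limma, adjusted p under 0.05), 1386 upward and 1171 downward, and 233 and 306 of them by at least 2-fold. In 37.2% of the tested genes the Tg and WT libraries did not overlap, where chance gives 10%. The authors' deposited table holds 2997 genes with an adjusted p-value under 0.05, and 2489 of the genes called here were among them in the same direction. Camera called 24 of 35 lists, 15 higher and 9 lower. With an estimated correlation camera called 0, with 7 at an unadjusted p under 0.05, and fry called 24. Limma called 1291 genes without WT_MPP replicate 1, 1138 without WT_MPP replicate 2, 1682 without Tg_MPP replicate 1 and 1218 without Tg_MPP replicate 2. Scaling to total reads moved the median of all genes by -0.13, and the list medians by about as much, and gave 787 genes upward and 2246 downward.

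**Figure D3:**
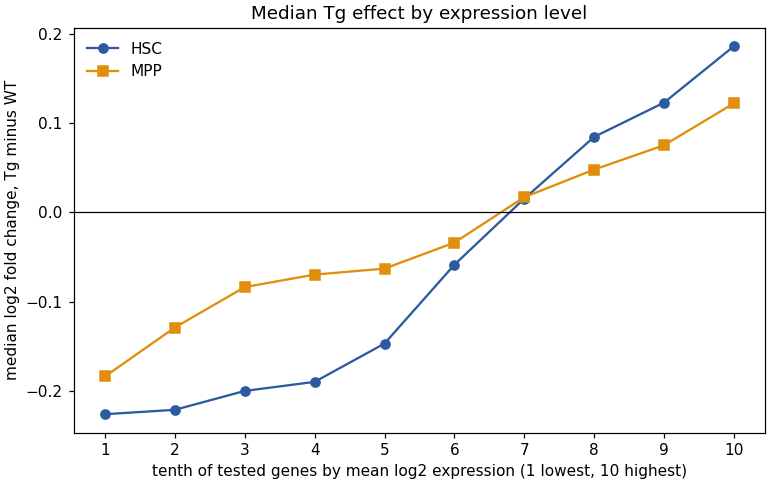
Median log2 fold change (Tg over WT) of the tested genes in 10 bins of mean expression, for HSC and for MPP. The medians run from -0.23 to 0.19 in HSC and from -0.18 to 0.12 in MPP.

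The series title sets HSC against MPP, so the effects of the transgene in both cell types were compared. They pointed largely the same way: 1040 genes rose in both and 761 fell in both, where independent calls would give 282 and 192. Opposite directions were found for 19 genes, where independent calls would give 465. As a difference, the log2 fold change in HSC minus that in MPP was taken. The globin genes Hbb-b1 (0.15, SE 0.27) and Hba-a1 (-0.029, SE 0.28) did not pass its test. The proliferation marker gene Mki67 had a higher effect in HSC, at 0.77 (SE 0.11, edgeR adjusted p = 0.0017).

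Across 14193 genes the effects had a Pearson r of 0.634 and a Spearman rho of 0.582, where genes are not independent replicates. Of 5250 genes that changed in HSC and were tested in MPP, 87.1% had the same sign in MPP, and the slope of MPP on HSC effects was 0.53. The shared counts upward and downward were 593 and 412 without WT_MPP replicate 1, 561 and 363 without WT_MPP replicate 2, and 545 and 414 without Tg_MPP replicate 2.

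The difference itself was tested on recovered reads with edgeR. The smallest p-values for a higher effect in HSC were those of Clnk (1.72, SE 0.17), Fcna (2.54, SE 0.26), Plek (1.04, SE 0.11), Oas3 (1.07, SE 0.11) and Mthfd2 (1.06, SE 0.12), with edgeR adjusted p from 3.37e-04 to 3.53e-04. Those for a lower effect were Lpar6 (-0.91, SE 0.1), Gstm1 (-0.85, SE 0.1), Adck3 (-0.65, SE 0.094), Ctsg (-0.99, SE 0.15) and Podxl (-2.12, SE 0.31), with edgeR adjusted p from 3.53e-04 to 0.00179. Clnk encodes an adaptor of immune receptors and Podxl a sialomucin of the cell surface. Of the fixed genes, Itga2b (0.75), Pf4 (1.22), Tfrc (0.82) and Cd34 (0.58) had higher effects in HSC, and Slamf1 (-0.66) a lower effect. For Tfrc the edgeR adjusted p was 0.0131, and 0.0577 without WT_HSC replicate 2 (from 4.55e-04 to 0.0577 over its alternatives).

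The calls of 5 other genes were kept in some of the 12 fits without 1 library and lost in the others. Klf1 (2.82, edgeR adjusted p = 0.0404, from 0.00141 to 0.102 over its alternatives) kept its call without WT_HSC replicate 3 or WT_MPP replicate 3. Flt3 (1.42, edgeR adjusted p = 0.0394, from 1.41e-04 to 0.101 over its alternatives) kept its call without WT_HSC replicate 3, WT_MPP replicate 1 or WT_MPP replicate 3. Gata1 (0.69, edgeR adjusted p = 0.0257, from 0.00461 to 0.0789 over its alternatives) kept its call without WT_HSC replicate 1, Tg_HSC replicate 1, WT_MPP replicate 1 or Tg_MPP replicate 2. Dntt (-0.89, edgeR adjusted p = 0.0413, from 0.00149 to 0.0999 over its alternatives) kept its call without WT_HSC replicate 2, Tg_HSC replicate 3, WT_MPP replicate 3 or Tg_MPP replicate 3. Mpo (-0.42, edgeR adjusted p = 0.0251, from 7.89e-04 to 0.0898 over its alternatives) kept its call without WT_HSC replicate 1 or 2, WT_MPP replicate 1 or 3, or Tg_MPP replicate 1 or 3. Cish (-0.34), Procr (-0.29) and Socs3 (0.16) did not pass. Neither did Vwf (-0.50), Epor (0.63), Gata2 (-0.32), Pim1 (0.63) and Cdkn1c (-0.53), although their calls differed between the cell types. For Epor the edgeR adjusted p was 0.066, and 0.0381 without WT_HSC replicate 1, 0.0349 without WT_MPP replicate 1 and 0.0415 without Tg_MPP replicate 2 (from 0.0323 to 0.18 over its alternatives). For Vwf it was 0.0673, and 0.0288 without Tg_HSC replicate 1 and 0.04 without WT_MPP replicate 3 (from 0.0254 to 0.157 over its alternatives). For Gata2 it was 0.191, and 0.0439 without WT_HSC replicate 1 (from 0.0439 to 0.385 over its alternatives).

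Camera on the differences called 13 lists, and 0 with an estimated correlation (5 at an unadjusted p under 0.05). Of the 45 measured S phase genes, 36 had a higher and 0 a lower effect in HSC, 42 and 0 adjusted over the list alone, with a median of 0.56. S phase genes had a camera adjusted p of 3.73e-30, and adjusted p = 0.164 with an estimated correlation. Among 52 genes of G2 and mitosis measured, 36 had a higher and 0 a lower effect in HSC, 47 and 0 adjusted over the list alone, with a median of 0.55. Genes of G2 and mitosis had a camera adjusted p of 4.04e-29, and adjusted p = 0.227 with an estimated correlation. Of the 25 measured terminal erythroid genes, 8 had a higher and 0 a lower effect in HSC, 14 and 0 adjusted over the list alone, with a median of 0.52. Terminal erythroid genes had a camera adjusted p of 7.37e-09, and adjusted p = 0.36 with an estimated correlation. Among 18 macrophage markers measured, 10 had a higher and 2 a lower effect in HSC, 12 and 2 adjusted over the list alone, with a median of 1.21. Macrophage markers had a camera adjusted p of 2.26e-07, and adjusted p = 0.291 with an estimated correlation. Of the 29 measured granulocyte-monocyte progenitor genes, 1 had a higher and 8 a lower effect in HSC, 1 and 11 adjusted over the list alone, with a median of -0.36. Granulocyte-monocyte progenitor genes had a camera adjusted p of 3.31e-05, and adjusted p = 0.316 with an estimated correlation. Among 81 cytosolic ribosomal protein genes measured, 0 had a higher and 3 a lower effect in HSC, 0 and 0 adjusted over the list alone, with a median of -0.34. Cytosolic ribosomal protein genes had a camera adjusted p of 2.02e-12, and adjusted p = 0.291 with an estimated correlation. Of the 40 measured stem cell identity genes, 1 had a higher and 6 a lower effect in HSC, 1 and 8 adjusted over the list alone, with a median of -0.13. Stem cell identity genes had a camera adjusted p of 0.00496, and adjusted p = 0.37 with an estimated correlation.

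Of 15470 genes, 1007 differed in their response (edgeR, adjusted p under 0.05), 785 with a higher and 222 with a lower log2 fold change in HSC. Of the 990 among them tested in both cell types, 829 had the larger absolute effect in HSC. The count was 573 without WT_HSC replicate 2, 514 without Tg_HSC replicate 2, 518 without Tg_HSC replicate 3, 437 without WT_MPP replicate 2 and 564 without Tg_MPP replicate 1. HSC cDNA was pre-amplified and MPP cDNA was not, so a difference in the response scale of the preparations stands beside the difference in cell type.

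**Figure D4:**
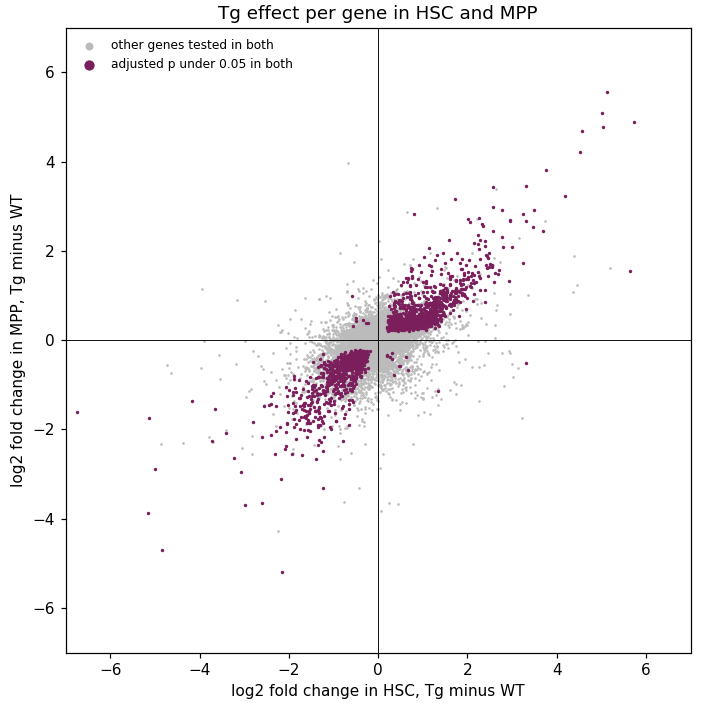
Log2 fold change (Tg over WT) of each gene tested in both cell types, MPP against HSC, across 14193 genes. The effects have a Pearson r of 0.634 across genes.

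WT MPP were compared with WT HSC as a check of the cell type labels. Progenitor genes were higher in WT MPP, with Flt3 at 287 ± 104 CPM in WT MPP against 26.2 ± 4.98 in WT HSC (log2 difference 3.53, SE 0.35). Cd34 was at 1419 ± 71.7 CPM in WT MPP against 367 ± 9.14 in WT HSC (log2 difference 2.03, SE 0.067, edgeR adjusted p = 6.05e-08). Stem cell genes were lower, with the surface receptor gene Slamf1 at 9.38 ± 0.491 CPM in WT MPP against 61.3 ± 1.38 in WT HSC (log2 difference -2.63, SE 0.1). Dntt (5.05) and Mpo (1.19) were also higher in WT MPP. Vwf (-3.07), Gata2 (-1.34), Procr (-1.22), Cdkn1c (-2.45), Cish (-1.56), Pf4 (-1.18), Itga2b (-0.62), Hbb-b1 (-1.06) and Hba-a1 (-0.79) were lower. Gata1 (-0.22), Klf1 (0.21), Tfrc (-0.029), Mki67 (0.041), Pim1 (0.09) and Socs3 (0.24) did not pass. Among 40 stem cell identity genes measured, 0 were higher and 34 lower in MPP, 0 and 34 adjusted over the list alone, with a median of -1.21. Stem cell identity genes had a camera adjusted p of 2.23e-25, and adjusted p = 0.00864 with an estimated correlation. Of the 28 measured megakaryocyte and platelet genes, 2 were higher and 20 lower in MPP, 2 and 20 adjusted over the list alone, with a median of -0.66. Megakaryocyte and platelet genes had a camera adjusted p of 2.52e-10, and adjusted p = 0.00864 with an estimated correlation. Among 12 multipotent progenitor markers measured, 11 were higher and 0 lower in MPP, 11 and 0 adjusted over the list alone, with a median of 1.37. Multipotent progenitor markers had a camera adjusted p of 1.66e-15, and adjusted p = 0.00864 with an estimated correlation. Of the 28 measured lymphoid priming genes, 19 were higher and 1 lower in MPP, 19 and 1 adjusted over the list alone, with a median of 0.91. Lymphoid priming genes had a camera adjusted p of 2.68e-11, and adjusted p = 0.00746 with an estimated correlation. Among 37 ribosome biogenesis genes measured, 26 were higher and 0 lower in MPP, 27 and 1 adjusted over the list alone, with a median of 0.39. Ribosome biogenesis genes had a camera adjusted p of 5.82e-12, and adjusted p = 0.0374 with an estimated correlation.

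Camera called 17 of the 35 lists in this comparison, and 5 with an estimated correlation. Of 14966 genes, 4333 differed (edgeR, adjusted p under 0.05), 2067 higher and 2266 lower in MPP. Without WT_MPP replicate 2 there were 2641. Cell type and the pre-amplification of the cDNA cannot be separated here.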

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

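Of the tests below, those of the 3 patterns were chosen only after the results were seen, and the splits of the libraries were planned. For 21 named genes the test of the difference itself set the transgene effect in HSC apart from that in MPP (log2 fold change in HSC minus that in MPP, edgeR adjusted p under 0.05). Higher effects in HSC were found for Clnk (1.72), Fcna (2.54), Plek (1.04), Oas3 (1.07), Mthfd2 (1.06), Gata1 (0.69), Klf1 (2.82), Tfrc (0.82), Itga2b (0.75), Pf4 (1.22), Cd34 (0.58), Flt3 (1.42) and Mki67 (0.77). Lower effects in HSC were found for Lpar6 (-0.91), Gstm1 (-0.85), Adck3 (-0.65), Ctsg (-0.99), Podxl (-2.12), Slamf1 (-0.66), Mpo (-0.42) and Dntt (-0.89). The calls of 6 of these genes ended without at least 1 library: of 12 such fits, Klf1 lost it in 10, Flt3 in 9, Gata1 in 8, Dntt in 8, Mpo in 6 and Tfrc in 1. Single libraries were not tested as outliers in groups of 3.

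The 6 libraries of a cell type can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In HSC 1 split, the real one, gave 5452 genes or more, and the highest other split gave 1; for gene lists 3 splits reached 18, the highest other with 18, so chance is not excluded by the list count. In MPP 1 split, the real one, reached 2557 genes (highest other 0) and 1 split 24 lists (highest other 17), and for WT MPP against WT HSC 1 split reached 4333 genes (highest other 0). For the difference of effects, 5 of 100 drawn splits, the real one included, reached 1007 genes, so chance is not excluded by this count. These splits point to the structure of the samples: 6410 genes were called with the genotypes swapped in MPP, and 3 others kept the HSC genotypes together and mixed those of MPP. Among the 80 splits that mixed the genotypes in both cell types the highest count was 1.

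The first pattern was the rise of all 25 measured terminal erythroid genes in Tg HSC and Tg MPP, of which 3 are also on other lists and 25 had a mean of at least 10 normalised reads in WT HSC, where Hbb-b1 was at 95283 ± 9649. RNA or cells of 1 erythroid source carried into both sorts would raise these genes in the same proportion, and the upper quartile of the ratios of the HSC to the MPP increase was larger than the lower by a factor of 1.47, just under a bound of 1.5 set after the values were seen (all ratios from 1.77 in Hba-a2 to 7.22 in Trim58). Of the 5 factor genes that rose in Tg HSC, Gata1, Gfi1b and Tal1 had at least the terminal genes' share in Tg MPP. Klf1 (-0.30) and Nfe2 (-0.045) lay 4.35 and 2.22 standard errors below it, but the Klf1 difference lost its call in 10 of 12 fits. As cDNA preparation differed, such a source and a shared erythroid programme cannot be told apart, and both remain open. For free RNA of red cells without a nucleus, the median of 10 erythroid transcription factor genes in Tg HSC was 0.34, which left it open, as Gata1 (1.73), Klf1 (2.46), Gfi1b (0.61), Tal1 (0.58) and Nfe2 (0.27) rose and Gata2 (-0.43), Lmo2 (-0.48), Ldb1 (-0.66) and Cbfa2t3 (-0.27) fell.

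The second pattern was the fall of 33 of 40 stem cell identity genes in Tg HSC. A share of cells that lack all of these genes would lower each by about the same amount, and the SD of the members' log2 fold changes was 5.58 times their median standard error, with Ly6a at -0.013, Tek at -0.0078 and Sult1a1 at -2.03, which argues against it as the whole cause. The trend with expression level (-0.23 to 0.19) was too small for this fall, so cyclic loess (list median -0.90) was no test. A change of stem cell state under the transgene and a mixture with 1 or several other cell types remain open and may both contribute.

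The third pattern was the rise of macrophage markers, 17 of 18 in Tg HSC, of which 4 are on other lists and 17 had a mean of at least 10 normalised reads in WT HSC. C1qb was at 1927 ± 224 against 315 ± 55.7 normalised reads in HSC and 1031 ± 213 against 359.5 ± 64.3 normalised reads in MPP, and Vcam1 at 4102 ± 454 against 870 ± 129 normalised reads and 1276 ± 254 against 1298 ± 247 normalised reads. If 1 macrophage source entered both sorts, each gene would rise in MPP by about the same share of its HSC increase, and 13 of the 16 that rose in HSC and were tested in MPP lay more than 2 standard errors from the median share, 6 below and 7 above. Only 4 of 25 terminal erythroid genes lay so far from theirs, the weakest, Trim58, among them, and most rose by more reads. A shared macrophage source stays open: preparation or change within MPP (Csf1r share 260%, Apoe -39%) may move shares. Macrophages carried into the HSC sort alone may also contribute: Mpeg1, which did not rise, was at -0.37 (limma adjusted p = 0.0753). That stays open, as does a macrophage-like programme in Tg HSC, which was not tested.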

How the results depend on the processing

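Scaling to total reads, cyclic loess and the limma fit of the difference on normalised values were chosen after seeing the data, and the other alternatives were planned. With all libraries kept, 60 counts of genes or lists stayed within 1.5 times their reported value and 9 did not. Requiring at least 2-fold left 1398 genes in HSC, 539 in MPP, 192 for the difference and 1202 for WT MPP against WT HSC, as fewer genes meet both conditions, and an adjusted p under 0.1 gave 1715 for the difference. DESeq2 gave 1531 and voom with quality weights 1571 genes for the difference, and limma on normalised values 905; the cause was not tested. Camera with an estimated correlation called 0 lists in HSC and 0 in MPP (10 and 7 at an unadjusted p under 0.05; fry 22 and 24), since each list then carries its own estimate of correlation. The correlation of effects was 0.582 as Spearman and 0.693 under the stricter filter, and the cause was not tested.

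Scaling to total reads turned the HSC log2 fold changes of Cd34 to -0.047 and of Mpo to -0.20, since it shifts every HSC gene by about -0.25. Cyclic loess turned them to -0.029 and -0.26; the cause was not tested. The HSC counts were 5178 genes under cyclic loess and 7090 under total reads, and the MPP counts 2351 and 3033. In MPP the median of niche adhesion genes was -0.0076 under TMM and -0.085 under cyclic loess. Among named genes, 2549 values kept their side of the threshold, without a reversal, with all libraries, 32 lost and 11 gained a call and 4 reversed, and among lists 543 did so, although some medians changed sign, 66 lost and 19 gained a call.

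Without 1 library the counts ran from 3853 (without Tg_HSC replicate 2) to 5322 (without WT_HSC replicate 1) in HSC, from 1138 (without WT_MPP replicate 2) to 3326 (without Tg_MPP replicate 3) in MPP, from 437 (without WT_MPP replicate 2) to 1395 (without WT_HSC replicate 1) for the difference and from 2641 (without WT_MPP replicate 2) to 4335 (without WT_HSC replicate 1) for WT MPP against WT HSC. The list counts ran from 17 (without WT_HSC replicate 2) to 21 (without WT_HSC replicate 3) in HSC and from 20 (without WT_MPP replicate 3) to 23 (without WT_MPP replicate 1) in MPP, and the correlation from 0.598 (without Tg_MPP replicate 3) to 0.636 (without WT_MPP replicate 2). The call ended without at least 1 library for 3 named genes in HSC, 9 in MPP and 6 for the difference. With the replicate number as a replicate block limma called 5413 genes in HSC and 1738 in MPP, although the labels do not say whether equal numbers pair the samples. The planned sex covariate was not run, because the reads of Xist placed all 12 libraries in 1 sex. In the simulated data 66 or 67 genes changed at each fold, far fewer than were called here. The shares called there do not give the sensitivity of these fits, and changes may have been missed.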

Other observations

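Several genes moved in the same direction in both cell types and were singled out after their values were seen. The glycolytic genes Aldoc (-1.56) and Eno2 (-1.52) fell in Tg HSC and Aldoc (-1.62) and Eno2 (-1.54) in Tg MPP, while their list did not pass in either cell type under the authors' scaling. In HSC it passed under cyclic loess, with a median of -0.18 (camera adjusted p = 0.0137; from 0.0137 to 0.747 over its alternatives). The cell cycle inhibitor gene Cdkn1a rose in Tg HSC (0.82) and in Tg MPP (1.01), as did Rb1, which restrains entry into S phase (0.95 and 0.65).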
